A study of Mus musculus with 23 samples.

How the data were processed

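The series holds 23 samples, of which 17 are single-cell expression libraries and 6 are contig tables labelled as T cell receptor libraries. Mice of the strain BL6 were 9.5 months old, and 2 of the 17 libraries came from mice treated with anti-CD4/CD8 antibodies or control IgG between 6 and 9.5 months of age. Per the labels, animals were perfused, cortex and hippocampus or meninges were dissociated, CD45-positive living cells were sorted by flow cytometry, and 8000 to 16000 cells were loaded for 5' single-cell libraries (10x Genomics) sequenced on a NovaSeq instrument. Sex was not labelled. E4, A-PE4 and TE4 are the mouse lines as the labels name them, and libraries were grouped by line, tissue, gate and treatment as the labels give them.

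The expression files hold raw UMI counts per gene and cell barcode, as deposited by the authors, with barcodes already called as cells and with no normalisation. The submitters' processing notes name Cell Ranger 6.1.1. Per the file headers, replicate 1 libraries of E4 and untreated TE4 were made with Cell Ranger 5.0.1, except E4 meninges replicate 1 with 3.1.0, and all others, with A-PE4 and the treated pair, with 6.1.1. The gene lists differed too, with 31055 genes in replicate 1 libraries of E4 and TE4 and in treated libraries, 31053 in replicate 2 libraries and 32285 in A-PE4 libraries. The lists of 31055 genes included human APOE and MAPT. The genome build was not given in the sources used here, so no positions are given. All comparisons used the 30406 genes present in every matrix. In E4 and untreated TE4 replicate number and gene list go together, and software version too except in the meninges, so replicate 1 and replicate 2 were taken as batches, and each A-PE4 library was a batch of its own. The counts of replicate libraries differed by more than sampling would give (chi-square per degree of freedom of 5.09 to 45.8), and no pair was identical.

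Barcodes with at least 300 genes and at most 10% mitochondrial counts were kept, 201772 in all. Doublet scores were simulated per library with scrublet as built into scanpy (expected rate 0.06). Its automatic threshold called hardly any doublets in the brain libraries, so a score over 0.2 was taken as a doublet, a limit set after the scores were seen. This called 8560 barcodes (4.24%), from 2.10% to 8.39% per library, and they were left out of the counts, shares and fits. Cells were scaled to equal depth, log-transformed and clustered over 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1.0, with seed 1, which gave 43 clusters. Lymphoid cells were clustered again over 20 components into 24 clusters. Each cluster was named from 27 marker classes fixed before the data were examined. The rules for naming were revised after the clusters were seen, to leave unnamed those of mixed markers, low depth or cells in division. Left out of all classes were clusters rich in called doublets (one of them with markers of both microglia and T cells), low-depth clusters near microglia, plasma cells and T cells, a cluster between B and immature B cells, and a cycling cluster. Unnamed cells made up 21.6% and 12.0% of E4, 3.86% of A-PE4, and 10.8% and 7.39% of TE4 cells in the brain CD45 total gate. In the CD45 high gate these shares were 8.85% and 7.14%, 21.8%, and 19.8% and 9.90%, and in the meninges 10.2% and 6.69%, 20.0%, and 8.44% and 7.02%.

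Counts were summed per library over the cells of a class, given at least 20 cells, and tested with the quasi-likelihood test of edgeR after TMM scaling and filterByExpr. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A-PE4 libraries stayed in each fit, where the lone A-PE4 library was assumed to vary like the others. Standard errors were taken from the fold change and its test statistic. Microglia came from the brain CD45 total gate, with 3067 to 14335 cells per untreated library, CD8 and CD4 T cells from the brain CD45 high gate, and CD8 T cells and border macrophages also from the meninges. Brain and meninges were compared over E4 and TE4 with 1 mean per line and tissue, and the difference of the TE4 effects as an interaction. Numbers of cells per class were tested with edgeR as well, with the kept cells as library size and adjustment over the classes of a gate. CD8 and CD4 subsets had a family of their own with the other classes. The single T cell share per gate also had an exact permutation test. The lists of genes, 28 in all, were fixed before the data were examined, 21 of them for microglia, 19 for T cells and 16 for macrophages. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The treated pair was described without a test, with exact counting intervals at 95% (Clopper-Pearson for shares) and 10000 random lists matched on expression.

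Genes named in the text follow a rule fixed with the lists. For each tested comparison it takes up to 4 members of each list with the smallest adjusted p and up to 6 higher and 6 lower genes with the largest changes among those called, with a mean of group CPMs of at least 20 and no overlap between the groups' libraries. It leaves out receptor segments and unnamed transcripts, and it always takes Prnp, Thy1, Apoe, Xist and Ddx3y. For the treated pair it takes up to 4 members per list with the largest ratio and the 6 highest and 6 lowest genes with at least 50 CPM in either library.

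The procedure was tested on simulated data made from the pseudobulk counts with known 2-fold and 4-fold changes. It recovered 74% and 90% of these in microglia, 65% and 93% in brain CD8 T cells, 69.7% and 99% in brain CD4 T cells, 60% and 94% in meningeal CD8 T cells, 33.3% and 89% in meningeal macrophages, and 78% and 93% in the comparison of tissues. False calls made up 7.87%, 12.2%, 4.55%, 8.33%, 14.1% and 6.56% of calls, above the nominal 5% in all but the brain CD4 T cells.

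Alternatives planned before the data were examined were DESeq2, RLE size factors, filters on low counts, stricter cell filters (800 genes, 5% mitochondrial counts), called doublets kept, clustering at resolution 2.0 (59 clusters), a block for the replicate number, E4 and TE4 libraries only, TMM scaling of cell classes, the CD45 total gate for T cells, and leaving out each library in turn. After the data were seen, a doublet score limit of 0.15, T-like unnamed clusters (at least 200 CPM of Cd3e) counted as T cells, B cell receptor clones, and counts without genes shifted in other classes were added. The planned T cell receptor clone result was not computed, since the contig tables used here held immunoglobulin chains and 0 contigs of T cell receptor alpha or beta chains. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.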

Results

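Single-cell RNA counts were measured in immune cells of 9.5-month-old mice of the lines E4, A-PE4 and TE4, the names the labels use. Cells of cortex and hippocampus (brain) or of the meninges were sorted on CD45, a surface protein of immune cells, in a total or a high gate. E4 and TE4 had 2 libraries each of the brain CD45 total gate, the brain CD45 high gate and the meninges, and A-PE4 had 1 library of each. A further pair of TE4 brain CD45 total libraries came from mice given antibodies against CD4 and CD8, which remove T cells, or control IgG. Total counts per library ran from 15736983 unique molecular identifiers (UMIs) in E4 brain CD45 total replicate 2 to 136779398 in TE4 meninges replicate 1. Nothing in the labels says that replicates came from separate animals, so each p-value measures only the spread between these libraries. In E4 and untreated TE4 libraries the replicate number coincides with the gene list of the files, so replicate 1 and replicate 2 were read as separate batches. It coincides with the software version as well, except that E4 meninges replicate 1 had another version than TE4 meninges replicate 1. Groups of E4 and TE4 hold 2 libraries each, and all A-PE4 values rest on 1 library.

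The first question was whether TE4 brains held more T cells. In the brain CD45 total gate, alpha-beta T cells made up 1.46% and 3.69% of cells in E4 replicates 1 and 2, and 4.47% and 8.47% in TE4 replicates 1 and 2. The mean share was 6.47% ± 2.83 (SD) in TE4 against 2.57% ± 1.58 in E4, and A-PE4 stood at 0.605%. CD8 T cells, the cytotoxic lineage, took most of these cells, with 3.67% and 6.96% in TE4 against 1.27% and 2.51% in E4. In the CD45 high gate, alpha-beta T cells held 57.8% and 53.7% in TE4, 40.9% and 38.8% in E4, and 28.3% in A-PE4. There the CD8 share was 44.5% ± 1.09 in TE4 and 27.5% ± 1.26 in E4, while the CD4 share averaged 6.44% in both lines. In the meninges the alpha-beta T cell share was 9.54% ± 0.281 in TE4, 7.96% ± 1.97 in E4 and 3.37% in A-PE4. Unnamed clusters that carry Cd3e, a T cell gene, in part droplets of 2 cell types or dividing cells, are not in these shares. Counting them as T cells gave 3.06% and 4.43% in E4, 3.75% in A-PE4, and 8.59% and 12.3% in TE4 in the CD45 total gate, so A-PE4 then lay between the E4 libraries. In the CD45 high gate it gave 47.9% and 43.8% in E4, 49.4% in A-PE4, and 77.3% and 63.2% in TE4, so A-PE4 then lay above E4, and in the meninges 8.11% and 11.2%, 5.17%, and 11.4% and 10.6%. The low A-PE4 share in the brain therefore depends on how these clusters are counted.

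None of these T cell shares passed the planned edgeR test, although TE4 was above E4 within each replicate number in both brain gates. The log2 difference was 1.34 ± 0.77 (SE) in the brain CD45 total gate (adjusted p = 0.501 over 17 classes). It was 0.49 ± 0.50 in the CD45 high gate (adjusted p = 0.477 over 19 classes) and 0.26 ± 0.34 in the meninges (adjusted p = 0.981 over 20 classes). The CD8 difference was 0.69 ± 0.47 in the CD45 high gate (adjusted p = 0.272) and did not pass in the CD45 total gate (adjusted p = 0.486). The edgeR test of shares pools the spread over the classes of a gate. The SEs and p-values of T cells therefore also reflect classes that varied more between libraries. In the CD45 high gate CD8 shares were 28.4% and 26.6% in E4 and 45.2% and 43.7% in TE4. Neutrophils there held 1.96% and 11.9% in TE4. An exact two-sided permutation test gave p = 0.333 in both brain gates, the smallest that 4 libraries allow, and p = 0.667 in the meninges. A fit with the replicate number as a term gave 1.41 (adjusted p = 0.104), 0.48 (adjusted p = 0.340) and 0.28 (adjusted p = 0.996) in the 3 gates. Counting the unnamed clusters with Cd3e as T cells gave 1.48 (adjusted p = 0.241), 0.62 (adjusted p = 0.417) and 0.19 (adjusted p = 0.981). With TMM scaling over the classes the CD45 high difference was 1.55 (adjusted p = 0.0389) and the CD8 difference there 1.56 (adjusted p = 0.0387).

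**Figure D1:**
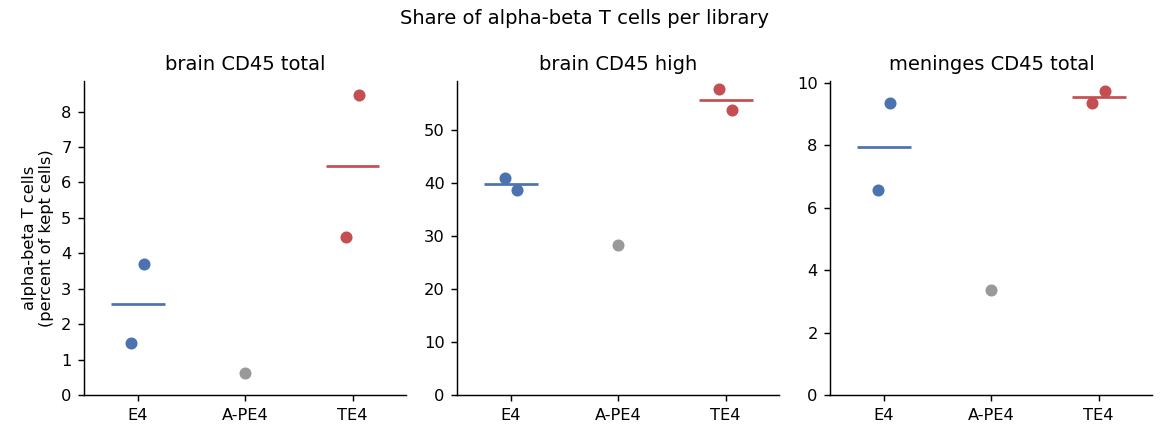
Share of alpha-beta T cells in percent of kept cells, 1 point per library and a bar at the mean, for E4, A-PE4 and TE4 in 3 gates. Both TE4 libraries lie above both E4 libraries in the brain CD45 total gate (4.47% and 8.47% against 1.46% and 3.69%) and in the brain CD45 high gate.

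Other classes of the brain CD45 high gate differed between TE4 and E4. Progenitor cells made up 0.291% ± 0.148 of cells in TE4 and 2.30% ± 0.0992 in E4 (log2 difference -2.97 ± 0.60, adjusted p = 2.3e-03). Immature B cells stood at 0.0199% against 0.321% (-3.91 ± 0.76, adjusted p = 2.3e-03), and basophils at 0.0189% against 0.288% (-3.79 ± 0.79, adjusted p = 2.3e-03). B cells held 2.48% ± 0.513 against 9.39% ± 0.782 (-1.92 ± 0.53, adjusted p = 0.0147), and ependymal and choroid plexus cells 0.0414% against 0.251% (-2.49 ± 0.79, adjusted p = 0.0285). Microglia, which mostly lie outside this gate, rose to 2.93% ± 0.415 from 0.879% ± 0.410 (1.74 ± 0.57, adjusted p = 0.0285), and A-PE4 had 11.4%. In the CD45 total gate ependymal and choroid plexus cells were higher in TE4, at 1.95% against 0.870% (1.15, adjusted p = 0.501). Progenitor (-1.98), immature B (-2.26), B cells (-1.03) and microglia (0.051) did not pass there. Immature B cells of the CD45 high gate were few in TE4, 0.0219% and 0.0180% of 9136 and 11133 kept cells. Shares of a gate sum to the whole, so differences between classes are not independent. The CD45 high calls for progenitor and immature B cells held in every setting run. The B cell call was lost with TMM scaling (-0.85, adjusted p = 0.226) and without E4 CD45 high replicate 1 (-1.84, adjusted p = 0.179) or E4 CD45 high replicate 2 (-2.01, adjusted p = 0.139). The microglia call was lost without E4 CD45 high replicate 1 (1.32, adjusted p = 0.396) or replicate 2 (2.31, adjusted p = 0.139), and the basophil call without E4 CD45 high replicate 1 (-3.31, adjusted p = 0.0667). The ependymal call was lost with TMM scaling (-1.42, adjusted p = 0.276), without E4 CD45 high replicate 1 (-2.81, adjusted p = 0.0688) or replicate 2 (-2.12, adjusted p = 0.194), and without TE4 CD45 high replicate 1 (-1.76, adjusted p = 0.0932).

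The second question was how microglia, the resident macrophages of the brain, differed between TE4 and E4. Genes known to rise in microglia around brain lesions were far higher in TE4. Cst7 (ENSMUSG00000068129), a protease inhibitor, was at 655 ± 27.8 CPM (counts scaled to a common library total) in TE4 against 13.2 ± 1.60 in E4 (mean ± SD, n = 2 each), a log2 fold change of 5.61 ± 0.19 (SE, adjusted p = 2.36e-09). Fabp5 (ENSMUSG00000027533), a fatty acid carrier, changed by 5.82 ± 0.18 (adjusted p = 2.36e-09), and the secreted matrix protein gene Spp1 (ENSMUSG00000029304) by 6.23 ± 0.24 (adjusted p = 3.53e-09), from 13.5 ± 1.31 to 1022 ± 281 CPM. The receptor kinase gene Axl changed by 4.73 ± 0.18 and the growth factor gene Igf1 by 6.22 ± 0.26. Gpnmb, a lysosomal glycoprotein gene, stood at 146 ± 101 CPM in TE4 and at 0.0691 ± 0.0977 in E4. All 23 tested genes of the disease-associated microglia list rose, with a median of 2.90 (camera adjusted p = 1.86e-112, adjusted p = 0.121 with an estimated correlation). Of the 16 homeostatic genes, which mark resting microglia, 7 fell and 1 rose (adjusted over the list alone, 10 and 1), with a median of -0.50 (camera adjusted p = 1.64e-04, adjusted p = 0.268 with an estimated correlation). P2ry12 (ENSMUSG00000036353), a nucleotide receptor of resting microglia, fell by 1.07 ± 0.18 on the log2 scale (adjusted p = 1.09e-03), from 3365 ± 187 to 1602 ± 326 CPM. The fructose transporter gene Slc2a5 fell by 1.18 ± 0.14 (adjusted p = 5.48e-05), and Sall1 (ENSMUSG00000031665), which encodes a transcription factor of microglial identity, fell by 0.91 ± 0.15 (adjusted p = 8.1e-04).

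Antigen presentation and interferon response genes rose together in TE4 microglia. All 20 tested interferon response genes rose (median 2.33, camera adjusted p = 2.95e-62, adjusted p = 0.121 with an estimated correlation), among them the antiviral membrane protein gene Ifitm3 (ENSMUSG00000025492) by 3.58 ± 0.16 (adjusted p = 1.36e-08), to 239 ± 38.8 from 19.9 ± 0.639 CPM. All 9 genes of MHC class II presentation, which shows antigen to CD4 T cells, rose (median 3.05, camera adjusted p = 1.95e-16, adjusted p = 0.121 with an estimated correlation). Cd74 (ENSMUSG00000024610), the class II invariant chain gene, went from 109 ± 4.38 to 1812 ± 605 CPM (4.05 ± 0.23, adjusted p = 1.05e-07), and H2-Aa (ENSMUSG00000036594), a class II chain gene, from 8.02 ± 1.67 to 320 ± 196 CPM (5.37 ± 0.38, adjusted p = 5.72e-07). Of the 12 MHC class I genes, which serve presentation to CD8 T cells, 11 rose (12 adjusted over the list alone, median 0.97, camera adjusted p = 3.62e-14, adjusted p = 0.121 with an estimated correlation), with H2-D1 up by 2.15 ± 0.17. Chemokine and cytokine genes rose for 12 of 17 (14 adjusted over the list alone, median 1.41, camera adjusted p = 5.61e-18, adjusted p = 0.121 with an estimated correlation). Ccl5, which attracts T cells, rose by 3.57 ± 0.17, Cxcl10, an interferon-induced attractant of T cells, by 2.30 ± 0.15, Cxcl16 by 1.90 ± 0.14, and the inflammatory cytokine gene Il1b by 2.90 ± 0.18.

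Further groups rose with these. Of 14 lysosome and phagocytosis genes 12 rose (13 adjusted over the list alone, median 0.98, camera adjusted p = 1.15e-14, adjusted p = 0.121 with an estimated correlation), with the lysozyme gene Lyz2 up by 2.81 ± 0.19 from 289 ± 51.4 CPM. Lipid handling genes rose for 11 of 12 (11 adjusted over the list alone, median 1.36, camera adjusted p = 8.26e-21, adjusted p = 0.121 with an estimated correlation), with the lipase gene Lpl up by 4.19 ± 0.20. Glycolysis genes rose for 10 of 11 (10 adjusted over the list alone, median 0.85, camera adjusted p = 3.51e-08) and complement genes for 7 of 10 (7 adjusted over the list alone, median 0.73, camera adjusted p = 3.82e-05). For both lists, adjusted p = 0.142 with an estimated correlation. Cell division genes did not move as a list (3 of 14 rose, camera adjusted p = 0.364), nor did mitochondrial transcripts (0 of 9, edgeR, camera adjusted p = 0.322). A cycling cluster was left out of all classes, so cell division genes, here and in later comparisons, were measured without its cells. Immediate early and dissociation response genes, which answer tissue handling, were lower for 6 of 14 (adjusted over the list alone, 8 lower and 1 higher, median -0.59, camera adjusted p = 1.21e-03, adjusted p = 0.523 with an estimated correlation).

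Markers of other cells moved in the same microglia. Of 10 brain parenchyma transcripts 6 rose (8 adjusted over the list alone, camera adjusted p = 1.7e-04, adjusted p = 0.220 with an estimated correlation), with the astrocyte gene Gfap at 3.61 ± 0.274 against 0.103 ± 0.0258 CPM. Of 8 border macrophage transcripts 4 rose (5 adjusted over the list alone, camera adjusted p = 1.77e-07, adjusted p = 0.201 with an estimated correlation), with Ms4a7 at 27.9 ± 0.561 against 1.77 ± 0.249 CPM, and 4 of 10 T cell transcripts rose (6 adjusted over the list alone, camera adjusted p = 0.0428, adjusted p = 0.653 with an estimated correlation), all under 1 CPM. Of 6 genes related to the promoters and targets of common transgenes, 2 rose (4 adjusted over the list alone, camera adjusted p = 0.0275, adjusted p = 0.369 with an estimated correlation), namely Prnp by 2.17 ± 0.23 and Apoe by 3.66 ± 0.67. The mouse Apoe entry stood at 734 ± 435 CPM in TE4 and 56.2 ± 62.5 in E4 and its call was lost without TE4 replicate 1 (2.88). The gene lists of the replicate 1 libraries also hold human APOE, at 14753 CPM in TE4 and 318 CPM in E4 microglia. The lists of replicate 2 and A-PE4 libraries lack it, so human reads may be counted as Apoe there, which was not tested. The rise of Apoe is therefore not shown to be one of the mouse gene. Of 6 B cell transcripts 2 rose (adjusted over the list alone, 2 higher and 1 lower), 1 of 3 erythrocyte transcripts, Hbb-bs, fell (1 adjusted over the list alone), and neutrophil and sex-linked transcripts gave 0 calls of 9 and 4 in edgeR, with Ddx3y, a Y-linked gene, at -0.21 ± 0.13 (adjusted p = 0.291). With the replicate number as a term, T cell transcripts no longer passed as a list (camera adjusted p = 0.106), though 7 were called higher. That fit called 1 neutrophil transcript higher and 3 lower. Microglia also differed in depth, with a median of 2718 and 3468 UMIs per cell in E4 replicates 1 and 2 and of 6007 and 3534 in TE4 replicates 1 and 2.

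Over all 14268 genes tested in these microglia, edgeR called 2894 as changed, 1792 higher and 1102 lower in TE4, of which 907 and 269 at least 2-fold. Of the 2894, 2887 had the same direction within each replicate number, and a fit with the replicate number as a term called 4540. Since calls came from the same libraries, agreement in direction, here and in later comparisons, is no separate check. The count was 1636 without TE4 replicate 1, 1860 without E4 replicate 1, and 1661 among genes with a group mean of at least 20 CPM. No list call of any comparison held with an estimated correlation. That setting bases the test on the residual degrees of freedom of the fit, 2 here and 4 where both tissues entered. With so few, small p-values were hardly within reach, so these values do not decide on the list calls. The fry test asks only whether a list moves in a single direction. It gave adjusted p = 0.0113 for the disease-associated list and 0.0383 for the homeostatic list.

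Clusters of microglia differed in their shares between the lines. P2ry12 and Tmem119 were among the leading genes of 2 clusters, whose shares differed in opposite directions. The one led by P2ry12 and Hspa1a held 45.3% and 64.0% of the microglia of E4 replicates 1 and 2, 38.9% in A-PE4, and 10.9% and 17.8% in TE4 replicates 1 and 2. The one led by Ier3 and Atf3 held 4.26% and 4.01% in E4, 27.3% in A-PE4, and 15.1% and 7.13% in TE4. A cluster of lower depth led by Ptpro and Tmx4 held 43.4% and 19.0% in E4, 6.00% in A-PE4, and 10.8% and 10.4% in TE4. A cluster led by Lpl, Csf1 and Spp1 held 0.858% and 1.30% in E4, 10.7% in A-PE4, and 31.5% and 30.6% in TE4. A cluster led by Spp1, Cst7 and Apoc1 held 5.97% and 11.3% in E4, 16.5% in A-PE4, and 30.8% and 33.2% in TE4. A small cluster led by Cxcl10 and Ifit3 held 0.209% and 0.391% in E4, 0.608% in A-PE4, and 0.836% and 0.813% in TE4. These cluster shares were not tested.

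**Figure D2:**
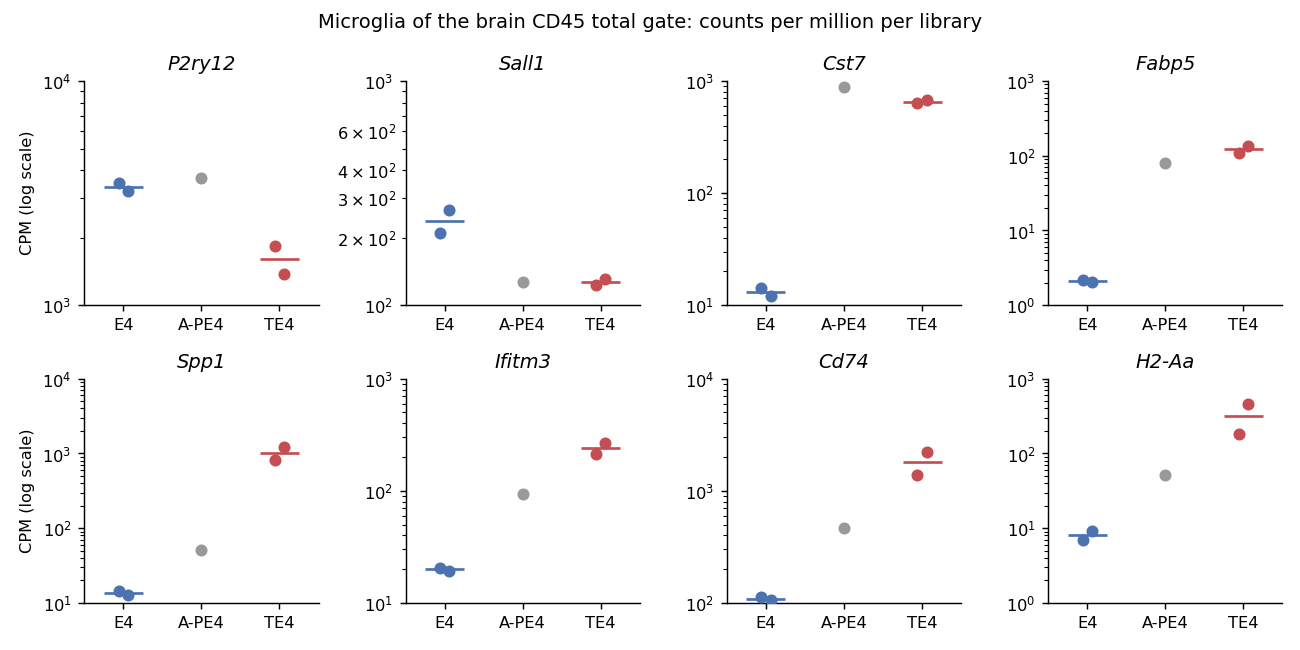
Expression in CPM on a log axis of 8 genes in microglia of the brain CD45 total gate, 1 point per library and a bar at the mean, for E4, A-PE4 and TE4. P2ry12 stands at 1602 CPM on average in TE4 against 3365 in E4, and Cst7 at 655 against 13.2.

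The third question set A-PE4 microglia against E4. Standard errors and p-values here assume that the lone A-PE4 library varies like the E4 and TE4 libraries, since its own spread is unknown. All 23 tested disease-associated genes rose in A-PE4 (23 adjusted over the list alone, median 1.71, camera adjusted p = 2.5e-76, adjusted p = 0.193 with an estimated correlation). Cst7 stood at 879 CPM in the single A-PE4 library (6.04 ± 0.20, adjusted p = 1.97e-09), Fabp5 at 80.5 CPM (5.23 ± 0.19, adjusted p = 3.98e-09), and Igf1 changed by 5.73 ± 0.28. Interferon response genes rose for 14 of 20 (18 adjusted over the list alone, median 1.17, camera adjusted p = 1.06e-22, adjusted p = 0.251 with an estimated correlation), with Ifitm3 up by 2.25 ± 0.17. MHC class II genes rose for 5 of 9 (8 adjusted over the list alone, median 1.12, camera adjusted p = 4.36e-09, adjusted p = 0.227 with an estimated correlation), with Cd74 at 466 CPM against 109 ± 4.38 in E4 (2.09 ± 0.24), and MHC class I genes for 6 of 12 (7 adjusted over the list alone, camera adjusted p = 2.34e-04, adjusted p = 0.273 with an estimated correlation). Of the 16 homeostatic genes only Sall1 passed, at -0.92 ± 0.19 (adjusted over the list alone, 1 lower and 2 higher, median -0.04, camera adjusted p = 0.583), and without E4 replicate 2 it no longer passed (-0.74, adjusted p = 0.0545). Chemokine and cytokine genes rose for 10 of 17 (10 adjusted over the list alone, camera adjusted p = 2.17e-09), lysosome genes for 9 of 14 (10 adjusted over the list alone, camera adjusted p = 4.71e-07), glycolysis genes for 7 of 11 (9 adjusted over the list alone, camera adjusted p = 6e-07) and lipid handling genes for 5 of 12 (adjusted over the list alone, 6 higher and 2 lower, camera adjusted p = 1.39e-09). For each of these 4 lists, adjusted p = 0.227 with an estimated correlation.

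All 9 mitochondrial transcripts were lower in the A-PE4 microglia (9 adjusted over the list alone, median -1.16, camera adjusted p = 1.35e-12, adjusted p = 0.227 with an estimated correlation). Several of the largest differences were in genes of general cell function, with Hgs up by 5.81 ± 0.21, Fam89b up by 5.43 ± 0.18 and Ptp4a1 at -5.79 ± 0.25. In the other cell classes the same 3 genes differed between A-PE4 and E4 libraries by a median of 4.81, 5.27 and -5.03. In total 1619 of 14268 genes passed, 1044 higher and 575 lower, and 4 microglial libraries of E4 and TE4 gave the spread. A-PE4 is 1 library with its own gene list, so its line and its batch cannot be told apart. Without the 90 called genes that differed at least 2-fold in other classes the count was 1529. Only 1319 of the 1619 had a value in other classes, so the 1529 include genes that could not be checked. With at least 800 genes and at most 5% mitochondrial counts per cell the count was 870, and among genes of at least 20 CPM 1053.

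TE4 microglia were then tested against A-PE4 directly. Of the 23 disease-associated genes 11 were higher in TE4 (15 adjusted over the list alone, median 0.69, camera adjusted p = 5.42e-19, adjusted p = 0.239 with an estimated correlation). Lgals3, which encodes a sugar-binding protein of phagocytes, was higher by 2.94 ± 0.20 (adjusted p = 1.85e-06) and Spp1 by 4.31 ± 0.29 (adjusted p = 1.89e-06), at 51.4 CPM in A-PE4. Interferon response genes were higher for 19 of 20 (19 adjusted over the list alone, median 1.26, camera adjusted p = 5.65e-23, adjusted p = 0.239 with an estimated correlation), with Ifi204 at 1.72 ± 0.19 and Ifitm3 at 1.34 ± 0.19. MHC class II genes were higher for 4 of 9 (5 adjusted over the list alone, median 1.83, camera adjusted p = 1.59e-05, adjusted p = 0.239 with an estimated correlation), among them Cd74 by 1.96 ± 0.28 and H2-Aa by 2.62 ± 0.42, and MHC class I genes for 5 of 12 (8 adjusted over the list alone, camera adjusted p = 1.91e-06, adjusted p = 0.239 with an estimated correlation). Of 17 chemokine and cytokine genes 8 were higher (adjusted over the list alone, 8 higher and 2 lower, camera adjusted p = 6.45e-05, adjusted p = 0.295 with an estimated correlation), with Ccl5 at 2.43 ± 0.20. Of 16 homeostatic genes 4 were lower in TE4 (5 adjusted over the list alone, median -0.32, camera adjusted p = 2.44e-04, adjusted p = 0.311 with an estimated correlation), Slc2a5 at -1.15 ± 0.16 and P2ry12 at -1.20 ± 0.22. The P2ry12 call was lost without TE4 replicate 2 (-0.98, adjusted p = 0.0926). In other cell classes E4 libraries stood below A-PE4 by more than this, with a median of -2.21 for P2ry12 and -1.47 for Tmem119. In microglia A-PE4 differed from E4 by 0.13 ± 0.22 for P2ry12 and -0.057 ± 0.20 for Tmem119. A shift shared by all A-PE4 cells could be masked there by an opposite difference in microglia, so these values do not settle its presence. Both are microglial marker genes, and microglia made up 11.4% of A-PE4 CD45 high cells against 0.589% and 1.17% in E4. In the CD45 total gate they held 91.7% against 72.2% and 76.4%, and in the meninges 0.315% against 0.0693% and 0.579%. Free microglial RNA in the other classes was not tested and cannot be told apart from such a shift. The border macrophage gene Ms4a7 stood at 4.22 and the immediate early gene Fos at -1.20 in TE4 against A-PE4 microglia. In other classes the median of E4 against A-PE4 was -0.77 for Ms4a7 and -1.83 for Fos. Glycolysis genes gave 0 calls of 11 in edgeR (camera adjusted p = 0.329). All 9 mitochondrial transcripts were higher in TE4 (9 adjusted over the list alone, median 1.43, camera adjusted p = 2.27e-18, adjusted p = 0.239 with an estimated correlation), and Hgs and Ptp4a1 differed by -5.77 and 5.30. In total 1172 genes passed, 641 higher and 531 lower. The count was 422 without TE4 replicate 2, 723 without TE4 replicate 1 and 562 among genes of at least 20 CPM, and the batch of the A-PE4 library stays confounded here too.

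**Figure D3:**
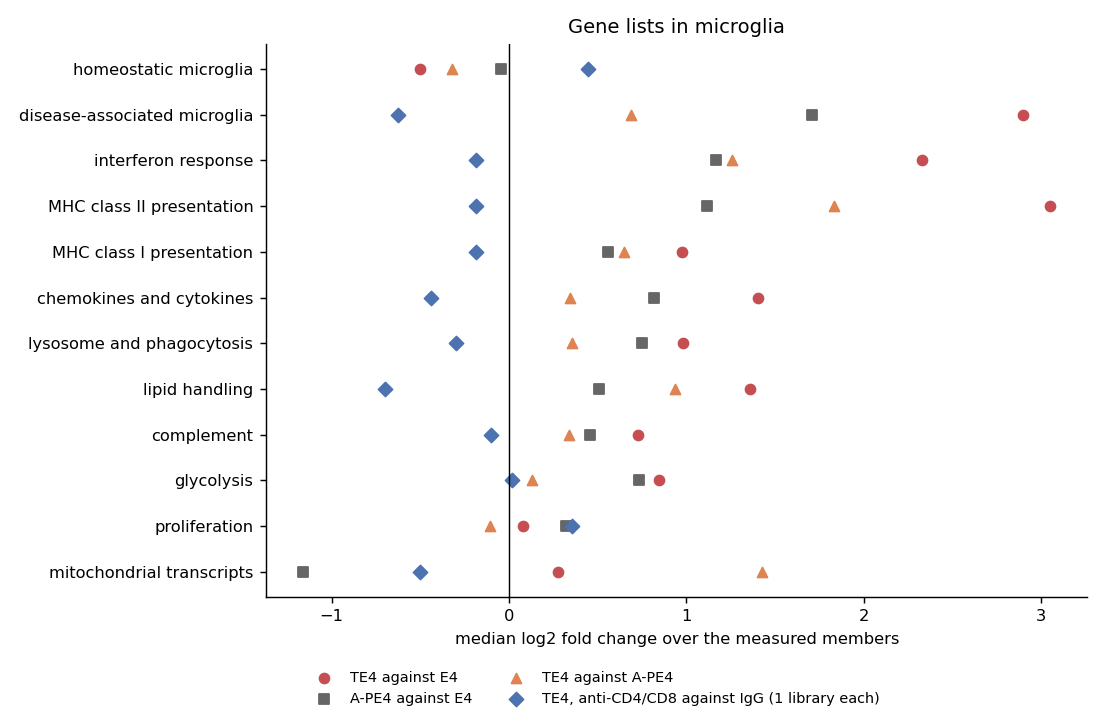
Median log2 ratio of each gene list in microglia for TE4 against E4, A-PE4 against E4, TE4 against A-PE4, and anti-CD4/CD8-treated against IgG-treated TE4, 1 point per list. The disease-associated list lies at 2.90, 1.71 and 0.69 in the 3 tested comparisons and at -0.63 in the treated pair.

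The next comparisons asked whether T cells differed in state between TE4 and E4. In CD8 T cells of the brain CD45 high gate 12 of 11790 genes passed, 3 of them neutrophil transcripts. Cdh1 (ENSMUSG00000000303), the adhesion molecule E-cadherin, rose by 1.27 ± 0.08 (adjusted p = 0.0304), to 72.8 ± 0.933 from 29.9 ± 2.30 CPM. Itgae (ENSMUSG00000005947), an integrin chain that binds E-cadherin and marks resident T cells, rose by 1.31 ± 0.13 (adjusted p = 0.0413), to 47.2 ± 7.01 from 19.0 ± 0.608 CPM. The interferon-induced genes Isg20 (ENSMUSG00000039236) and Ifi44 rose by 1.07 ± 0.10 (adjusted p = 0.0413) and 1.31 ± 0.14 (adjusted p = 0.0499), and Ckb, a creatine kinase gene, by 1.04 ± 0.11 (adjusted p = 0.0499). As a list, interferon response genes were higher (1 of 20, 10 adjusted over the list alone, median 0.44, camera adjusted p = 2.74e-22, adjusted p = 0.406 with an estimated correlation). Naive and memory T cell genes were lower (0 of 10 in edgeR, 7 adjusted over the list alone, median -0.49, camera adjusted p = 1.4e-18, adjusted p = 0.239 with an estimated correlation). Of these, the chemokine receptor gene Ccr7 stood at -1.12 ± 0.15 (adjusted p = 0.0969). Effector and cytotoxic genes (0 of 16 in edgeR, camera adjusted p = 0.145) and inhibitory receptor genes (0 of 12 in edgeR, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.484) did not pass, with Gzmb at 0.43 ± 0.18 and Lag3 at 0.40 ± 0.10. Tissue residency genes gave 1 call of 11 (adjusted over the list alone, 1 higher and 1 lower, camera adjusted p = 0.0262, adjusted p = 0.606 with an estimated correlation). Neutrophil transcripts fell for 3 of 9 (8 adjusted over the list alone, median -3.25, camera adjusted p = 2.09e-43, adjusted p = 0.239 with an estimated correlation), with S100a9 at -3.38 ± 0.30 and 136 ± 40.7 CPM in E4. Microglial transcripts gave 0 calls of 10 in edgeR (median 0.45, camera adjusted p = 1.7e-04, adjusted p = 0.606 with an estimated correlation).

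Of the 12 calls in brain CD8 T cells 7 were higher and 5 lower, each in the same direction within both replicate numbers, and 1027 genes had an unadjusted p under 0.05. DESeq2 called 88 and a fit with the replicate number as a term 242. That fit called 11 interferon response and 6 microglial genes higher and 5 naive and memory and 7 neutrophil genes lower. In it 3 further lists were lower by camera. These were B cell transcripts (median -0.84, adjusted p = 1.38e-03), brain parenchyma transcripts (-0.63, adjusted p = 2.42e-04) and cell division genes (-0.26, adjusted p = 1.13e-03). Leaving out E4 replicate 1, E4 replicate 2 or TE4 replicate 2 left 1 call and leaving out TE4 replicate 1 left 3, and each gene named here lost its call in all 4 cases, Cdh1 with an adjusted p between 0.0619 (without E4 replicate 2) and 0.103 (without TE4 replicate 2). In CD8 T cells of the CD45 total gate, with 101 to 600 cells per E4 and TE4 library, edgeR called 0 of 9365 genes, with 493 at an unadjusted p under 0.05, and Ckb turned direction there (-0.065).

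CD4 T cells, the helper lineage, were tested in the CD45 high gate as well. Itgae rose by 3.11 ± 0.39 (adjusted p = 4.42e-03), to 35.7 ± 5.97 from 5.29 ± 4.19 CPM, the chemokine gene Cxcl10 (ENSMUSG00000034855) by 1.81 ± 0.21 (adjusted p = 2.63e-03), to 56.7 ± 9.48 from 15.7 ± 2.17 CPM, and the interferon-induced gene Rtp4 by 0.93 ± 0.15 (adjusted p = 0.0386). Interferon response genes were higher as a list (1 of 19, 13 adjusted over the list alone, median 0.57, camera adjusted p = 1.65e-23, adjusted p = 0.168 with an estimated correlation). Regulatory T cell genes were higher as a list (0 of 5 in edgeR, 4 adjusted over the list alone, median 1.12, camera adjusted p = 3.11e-10, adjusted p = 0.391 with an estimated correlation), with Foxp3, the defining factor of regulatory T cells, at 60.1 ± 24.1 against 26.3 ± 9.51 CPM (1.30 ± 0.30, adjusted p = 0.184). Neutrophil transcripts fell for 4 of 7 (7 adjusted over the list alone, median -2.83, camera adjusted p = 4.32e-54, adjusted p = 0.168 with an estimated correlation), S100a8 (ENSMUSG00000056054) by 3.01 ± 0.23 (adjusted p = 1.2e-04). Microglial transcripts rose for 3 of 9 (5 adjusted over the list alone, camera adjusted p = 4.42e-14, adjusted p = 0.343 with an estimated correlation), namely C1qa, C1qb and C1qc. In all 19 of 10097 genes passed, 10 higher and 9 lower, with 655 at an unadjusted p under 0.05 and 7 by DESeq2. All 19 had the same direction within both replicate numbers, and a fit with the replicate number as a term called 134. That fit called 9 interferon response, 4 regulatory T cell and 4 microglial genes higher and 5 neutrophil genes lower. The count was 12 without E4 replicate 1, 49 without E4 replicate 2, 137 without TE4 replicate 1 and 75 without TE4 replicate 2. Without E4 replicate 1 the calls for Itgae (2.11, adjusted p = 0.128), Rtp4 (0.68, adjusted p = 0.411) and C1qa, C1qb and C1qc (adjusted p = 0.526, 0.576 and 0.496) were lost, and the Cxcl10 call was lost in DESeq2 (adjusted p = 0.0641).

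In the meninges no gene passed between TE4 and E4 in the planned edgeR test, while a fit with the replicate number as a term called a few. In meningeal CD8 T cells edgeR called 0 of 9918 genes, with 241 at an unadjusted p under 0.05, 3 by DESeq2 and 16 with the replicate term. Ifi44 stood at 12.9 ± 3.73 against 3.96 ± 0.329 CPM and Lag3 at 31.0 ± 1.31 against 49.5 ± 15.9 CPM. Retnlg (ENSMUSG00000022651), a neutrophil gene, had a log2 difference of 1.88 ± 0.26 (adjusted p = 0.496). Neutrophil transcripts were higher as a list (1 of 9 adjusted over the list alone, median 0.47, camera adjusted p = 4.06e-06, adjusted p = 0.686 with an estimated correlation) and cell division genes lower (0 of 13 adjusted over the list alone, median -0.25, camera adjusted p = 4.0e-03, adjusted p = 0.686 with an estimated correlation). Erythrocyte transcripts were lower as a list (0 of 5 adjusted over the list alone, median -1.93, camera adjusted p = 4.34e-07, adjusted p = 0.686 with an estimated correlation). In meningeal border macrophages, the resident macrophages of that tissue, edgeR called 0 of 10760 genes, with 218 at an unadjusted p under 0.05, 8 by DESeq2 and 3 with the replicate term. The division genes Mki67 (ENSMUSG00000031004) and Top2a stood lower, Mki67 at 35.9 ± 11.4 against 113 ± 5.64 CPM (-1.60 ± 0.22, adjusted p = 0.961) and Top2a at -1.67 ± 0.24 (adjusted p = 0.961). The list of 14 cell division genes was lower (5 adjusted over the list alone, median -0.79, camera adjusted p = 8.95e-26, adjusted p = 0.454 with an estimated correlation), but at the finer clustering Mki67 was at 0.05. Cells of the cycling cluster were left out here too. T cell transcripts were higher in these macrophages (3 of 10 adjusted over the list alone, median 0.62, camera adjusted p = 9.94e-11, adjusted p = 0.454 with an estimated correlation). Transcripts of other cells were lower, with 0 calls adjusted over the list alone for neutrophil (9 genes, median -1.48, camera adjusted p = 6.41e-05), B cell (7 genes, median -1.01, camera adjusted p = 4.18e-06) and erythrocyte transcripts (5 genes, median -1.53, camera adjusted p = 2.13e-05), each at an adjusted p = 0.468 with an estimated correlation. The CD8 T cells gave 11 calls without E4 meninges replicate 1, 5 without E4 meninges replicate 2, 9 without TE4 meninges replicate 1 and 7 without TE4 meninges replicate 2. The macrophages gave 5, 7, 2 and 1 calls without the same libraries, in the same order.

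CD8 T cells of the brain were also compared with those of the meninges, over E4 and TE4 together. Naive and memory genes were lower in the brain for 9 of 10 (9 adjusted over the list alone, median -1.35, camera adjusted p = 4.76e-26, adjusted p = 0.0583 with an estimated correlation). Of these, S1pr1, a receptor for leaving tissue, had a log2 difference of -1.64 ± 0.12. Tissue residency genes were higher for 7 of 11 (8 adjusted over the list alone, median 0.89, camera adjusted p = 1.94e-13, adjusted p = 0.0583 with an estimated correlation), with Rgs1 at 2.10 ± 0.19 and Itgae at 2.03 ± 0.19. Effector genes were higher for 6 of 16 (6 adjusted over the list alone, median 0.15, camera adjusted p = 7.19e-07, adjusted p = 0.0962 with an estimated correlation). Ifng (ENSMUSG00000055170), the gene of interferon gamma, was at 332 ± 85.6 CPM in the brain against 36.3 ± 11.4 in the meninges (n = 4 each, 3.25 ± 0.26, adjusted p = 1.96e-04), and the chemokine gene Ccl3 was higher by 1.57 ± 0.12. Inhibitory receptor and exhaustion genes were higher for 8 of 12 (8 adjusted over the list alone, median 0.57, camera adjusted p = 4.64e-09, adjusted p = 0.154 with an estimated correlation), among them Nr4a2 by 4.02 ± 0.33 and Ctla4 by 2.77 ± 0.26. Cell division genes were lower for 5 of 14 (6 adjusted over the list alone, camera adjusted p = 3.81e-03, adjusted p = 0.0925 with an estimated correlation).

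The same cells differed in genes of tissue handling and in markers of other cells. Whether tissue handling contributed to the residency, effector and inhibitory receptor differences was not tested. Immediate early and dissociation response genes were higher in the brain for 11 of 14 (11 adjusted over the list alone, median 2.58, camera adjusted p = 1.32e-26, adjusted p = 0.0583 with an estimated correlation), with Fos (ENSMUSG00000021250) higher by 5.80 ± 0.56 (adjusted p = 3.74e-04), at 690 ± 272 CPM in the brain. Neutrophil transcripts were lower in the brain for all 9 (9 adjusted over the list alone, median -3.35, camera adjusted p = 4.74e-21, adjusted p = 0.0583 with an estimated correlation), B cell transcripts for 5 of 7 (7 adjusted over the list alone, camera adjusted p = 5.02e-09, adjusted p = 0.0583 with an estimated correlation) and erythrocyte transcripts for all 5 (5 adjusted over the list alone, camera adjusted p = 8.9e-11, adjusted p = 0.0925 with an estimated correlation). In a fit with a term for each line and replicate number, 8 mitochondrial transcripts were lower in the brain (list median -0.37, camera adjusted p = 5.76e-06). That fit called 6 microglial transcripts higher (list median 0.57, camera adjusted p = 9.05e-04). In the planned fit 2357 of 11504 genes passed, 1183 higher and 1174 lower in the brain, of which 211 and 372 at least 2-fold. Within each genotype and replicate number 2253 of the 2357 kept their direction. The gates also differed, CD45 high in the brain and CD45 total in the meninges. DESeq2 called 1243, and the count was 1236 without E4 CD45 high replicate 1, 1304 without TE4 CD45 high replicate 1, 1372 without TE4 CD45 high replicate 2 and 1335 without TE4 meninges replicate 1.

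The difference of the TE4 effect on CD8 T cells between brain and meninges was tested as an interaction. It passed for 1 gene, Retnlg, a secreted protein gene of neutrophils, at -4.77 ± 0.38 (adjusted p = 6.71e-03), with 583 genes at an unadjusted p under 0.05 and 15 calls by DESeq2. Neutrophil transcripts as a list had a median of -3.83 (1 of 9, 8 adjusted over the list alone, camera adjusted p = 2.27e-51, adjusted p = 0.0518 with an estimated correlation). A fit with the replicate number as a term gave 15 calls and called 6 neutrophil genes lower. The Retnlg call was lost with called doublets kept (-5.04, adjusted p = 0.0899), at the finer clustering (-2.22), without E4 CD45 high replicate 1 (-4.56, adjusted p = 0.106) and without TE4 meninges replicate 1 (-4.83, adjusted p = 0.0863) or replicate 2 (-4.69, adjusted p = 0.0820). The count of calls was 4 without E4 CD45 high replicate 2 and 2 without E4 meninges replicate 1. Itgae did not pass (1.22 ± 0.43, adjusted p = 0.972), so the TE4 effect on it is not shown to differ between the tissues. Interferon response genes had a median of 0.31 (0 of 20 in edgeR, 1 adjusted over the list alone, camera adjusted p = 2.94e-06, adjusted p = 0.793 with an estimated correlation) and naive genes one of -0.59 (0 of 10 in edgeR, 2 adjusted over the list alone, camera adjusted p = 4.81e-07, adjusted p = 0.613 with an estimated correlation).

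The last comparison asked what followed T cell depletion in TE4, given from 6 to 9.5 months of age. It sets 1 library against 1, so its values carry no test and its intervals (exact, 95%) cover counting error only. Alpha-beta T cells were 413 of 12652 cells (3.26%, Clopper-Pearson interval 2.96 to 3.59) in the IgG-treated library and 80 of 14791 (0.541%, 0.429 to 0.673) in the anti-CD4/CD8-treated library, a ratio of 6.04 (4.74 to 7.77). With the unnamed clusters that carry Cd3e counted as T cells the shares were 6.25% and 2.81%, a ratio of 2.23 (1.98 to 2.52). Of these 378 and 335 unnamed cells, 66 and 191 were in the cycling cluster and 270 and 103 in the cluster with markers of both microglia and T cells. CD8 T cells went from 2.28% to 0.433%, a ratio of 5.28 (4.01 to 7.03). CD4 T cells were 51 cells (0.403%) with IgG and 0 of 14791 with the antibodies, which at 95% allows up to 0.0249%, a ratio of at least 15.6. Gamma-delta T cells, which neither antibody targets as a class, were at 0.443% and 0.642%, NK cells at 0.427% and 0.189%, and microglia at 89.9% and 92.5%.

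Microglia of the anti-CD4/CD8-treated library had more homeostatic and fewer disease-associated transcripts. Of the 16 homeostatic genes 15 were higher than with IgG, with a median log2 ratio of 0.45 (0.44 to 0.46), and P2ry12 went from 1579 to 2989 CPM (0.92, 0.91 to 0.93). All 23 disease-associated genes were lower, with a median of -0.63 (-0.65 to -0.60), among them Gpnmb from 79.7 to 8.02 CPM (-3.31, -3.44 to -3.18) and Igf1 by -2.61. Lipid handling genes were lower for 12 of 12 (median -0.70), lysosome genes for 13 of 13 (-0.30), with Lyz2 from 1646 to 688 CPM, and chemokine and cytokine genes for 13 of 17 (-0.44), while Cxcl13 was higher by 1.20. Interferon response genes were lower for 14 of 20 (-0.18), MHC class II genes for 5 of 8 (-0.18) and MHC class I genes for 9 of 12 (-0.19), with Cd74 from 1308 to 955 CPM (-0.45). Each of these medians lay outside the 95% range of 10000 random lists matched on expression, while glycolysis (0.02) and complement (-0.10) genes lay inside. Cell division genes were higher for 7 of 8 (0.36) and immediate early genes for 13 of 14 (0.19). Cells of the cycling cluster were not among these microglia.

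Transcripts of other cells and of RNA quality moved in this pair too. Mitochondrial transcripts were lower for 9 of 9 (-0.50), border macrophage transcripts for 4 of 4 (-2.00) and parenchyma transcripts for 5 of 7 (-0.59). Neutrophil transcripts were higher for 6 of 7 (1.85) and B cell transcripts for 2 of 2 (0.52), and sex-linked transcripts were at -0.21. Of 1568 measured genes that were higher in TE4 than in E4 microglia, 1350 (86.1%) were lower with the antibodies, with a median of -0.26. Of 1007 that were lower in TE4, 922 were higher, with a median of 0.31. The median of all genes was 0.03. No statement on animals can be made from this pair, since the spread between libraries treated alike is unknown.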

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

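The tests of mitochondrial transcripts in other classes and of neutrophil transcripts in other classes were chosen only after the result was seen. For the A-PE4 gene comparisons the reading of the planned tests was changed, after the values were seen, from the point value to its 95% bootstrap interval, which altered no outcome.

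The TE4 effect on Retnlg in CD8 T cells differed between brain and meninges in a test of the difference itself (log2 -4.77 ± 0.38, adjusted p = 6.71e-03), a call lost with called doublets kept, at the finer clustering (-2.22) and without any 1 of 3 libraries (E4 CD45 high replicate 1, TE4 meninges replicate 1 and TE4 meninges replicate 2). Neutrophil transcripts as a list had a median of -3.25 in brain CD8 T cells, and over 8 other classes of the CD45 high gate one of -2.77 in TE4 replicate 1 (range -4.03 to -1.88) and -1.90 in TE4 replicate 2 (range -3.64 to 2.08). The list also fell in B cells (-2.65 and -2.50 in TE4 replicates 1 and 2) and NK cells (-2.40 and -2.77), so the fall was not confined to T cells. In TE4 replicate 2 it rose only in cDC2 dendritic cells (2.08) and monocytes (0.25), and stood at -1.12 in neutrophils themselves. Free RNA of neutrophils and a change in the T cells cannot be told apart, since the classes of TE4 replicate 2 went both ways and neutrophils made up 11.9% of its cells (1.96% in TE4 replicate 1, 13.3% and 14.2% in E4). Leaving out droplets over a doublet score of 0.15 gave -3.26 in CD8 T cells. This argues against droplets over that score, holding both a neutrophil and a T cell, as the source. Mixed droplets with lower scores stayed in and are not excluded. No biological explanation in the T cells was tested, and the level of free RNA in empty droplets is not known, since only called cells were used here.

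The A-PE4 microglia library differed from E4 in 1619 genes while also being a batch of its own. The mitochondrial list, lower in A-PE4 microglia, had a median of -1.16 over 24 other classes and gates (-1.59 to -0.68), which is consistent with a difference between library batches and argues against an effect in microglia alone. For the 1319 called genes with a value elsewhere, the shift in other classes was 0.313 of that in microglia (0.291 to 0.334), so line and batch cannot be told apart for these genes as a whole, since the design gives A-PE4 a single batch. For the 370 of them that changed at least 2-fold the shift was 0.173 (0.119 to 0.217), and 82 of these differed at least 2-fold elsewhere, which does not settle it either. For the 23 disease-associated genes the shift was 0.0808 (-0.00728 to 0.191), which argues against a batch or gene list difference shared by all cells as the source for this list as a whole. Of the 23, 1 gene differed at least 2-fold elsewhere, namely Apoe (2.99 in microglia, a median of 1.72 over 9 other classes and gates). A batch difference in microglia alone and an A-PE4 effect stay open.

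Human APOE and MAPT, present in the gene lists of some libraries, gave counts that no comparison used. In the brain CD45 total libraries of replicate 1, human APOE in microglia stood at 14753 CPM in TE4 (93.5% of cells, median 6065 UMIs) and 318 CPM in E4 (19.3%, median 2721 UMIs). In alpha-beta T cells of the same TE4 library it was found in 69.9% of cells (median 5132 UMIs). The CPM in microglia was 30.6 times that in T cells, which argues against free RNA spread evenly over droplets as the main source. B and NK cells there stood at 676 and 262 CPM, but neutrophils and monocytes at 3518 and 2341 CPM, closer to microglia. T cells stood at 483 CPM in TE4 and 10.2 in E4, so free RNA as a part of the counts stays open. Within the 6 microglia clusters the ratio of TE4 to E4 had a median of 15.8 (4.43 to 45.2), which argues against a shift of cells between clusters. A higher level per cell in TE4 may remain as a hypothesis, with 1 library per line and batch and line differences in the animals untested. In the brain CD45 high libraries human APOE in microglia stood at 37801 CPM in TE4 (241 cells) and 7785 CPM in E4 (43 cells only).

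Human MAPT UMIs numbered 14 in the TE4 brain CD45 total library of replicate 1, 101 in the TE4 meninges library of replicate 1, 2 in the TE4 brain CD45 high library of replicate 1, 3 in the IgG-treated library and 11 in the anti-CD4/CD8-treated library, against 0 in the 3 E4 libraries of replicate 1. The contig tables, whose immunoglobulin chains no comparison used, placed 22.9% of paired cells in B cell receptor clones of 2 or more cells in the TE4 brain (18.6 to 27.6, Clopper-Pearson 95%) against 11.2% in the table labelled E4 brain (7.65 to 15.5). One clone held 57 of the 80 clonal TE4 cells, and outside the largest clone of each table the shares were 7.85% (5.04 to 11.5) in TE4 and 9.13% (5.93 to 13.3) in the table labelled E4, so the brain difference rests on that clone. In the meninges the share was 11.7% in TE4 (10.3 to 13.2) against 5.73% in the table labelled E4 meninges (4.84 to 6.73), and 10.1% (8.84 to 11.6) against 4.63% (3.82 to 5.55) outside the largest clones. Each is 1 table, barcodes of the E4 brain table matched no library by more than 3.85% and those of the E4 meninges table none by more than 3.08%, so neither E4 value is shown to come from the E4 libraries, and 91 of 372 barcodes of the TE4 brain table were found among cells of the E4 meninges replicate 1 library.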

How the results depend on the processing

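The doublet limit of 0.15, the T-like clusters counted as T cells and the counts without genes shifted in other classes were alternatives chosen only after the data were seen. Over 2975 settings of 215 named genes, 2738 kept direction and side of the threshold, 140 lost and 85 gained a call and 12 turned direction. The cause was not tested for any value below unless named. Without 1 library each the counts of called genes ran from 1636 to 2489 (microglia TE4 against E4), 422 to 1413 (TE4 against A-PE4), 1 to 3 (brain CD8), 12 to 137 (brain CD4), 5 to 11 (meningeal CD8), 1 to 7 (meningeal macrophages), 1236 to 2110 (brain against meninges) and 0 to 4 (interaction), in fits where the lone library left is assumed to vary like the others. With the replicate block the counts were 4540 (microglia), 242, 134, 16 and 3 (brain CD8, brain CD4, meningeal CD8, macrophages) and 15 (interaction). The replicate numbers are not said to pair libraries, and deviations of replicate 1 correlated across genes at 0.27 in microglia, 0.29 in brain CD8, 0.14 in brain CD4 and meningeal CD8 T cells and 0.10 in meningeal macrophages. DESeq2 called 88, 7, 3, 8, 1243 and 15 in brain CD8, brain CD4, meningeal CD8, macrophages, tissues and interaction. Without a count filter the counts were 525, 152, 112, 183 and 158 for brain CD8, brain CD4, meningeal CD8, macrophages and interaction. At 20 CPM or more, with fewer genes tested, they were 1661, 1053 and 562 in the microglia comparisons, 7 and 10 in brain CD8 and CD4, and 2 in the interaction. Stricter cell filters gave 870 for A-PE4 against E4 and 4 for the interaction, resolution 2.0 gave 5 and 7 in brain CD8 and CD4 and 0 in the interaction, kept doublets 0 and the 0.15 limit 4 in the interaction. T cells of the CD45 total gate gave 0 (CD8) and 2 (CD4) calls with edgeR.

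With TMM scaling the T cell share of the CD45 high gate passed (1.55). The IgG T cell share was 3.77% under stricter cell filters and 6.25% with the T-like clusters counted, and the anti-CD4/CD8 share then 2.81%. In the treated pair TMM scaling gave list medians of 0.43 (homeostatic), -0.21 (interferon), -0.46 (chemokines), -0.32 (lysosome), 0.17 (immediate early) and -0.52 (mitochondrial), and kept doublets -0.66 (disease-associated), -0.21 (interferon) and -0.44 (chemokines). Directions turned for Ckb in CD8 T cells of the CD45 total gate (-0.065), for Gzmk (-0.056) and Thy1 (0.32) in CD4 T cells there, and at resolution 2.0 for Ddx3y in brain CD4 T cells (-0.014) and Mki67 in meningeal macrophages (0.051). Without 1 library each, Apoe in TE4 against A-PE4 microglia ran from -0.075 to 1.21, Ddx3y from -0.074 to 0.13 in brain CD8, from -0.082 to 0.14 in brain CD4 and from -0.047 to 0.57 in meningeal macrophages, Thy1 from -0.087 to 0.037 in brain CD4 and from -0.11 to 0.016 in meningeal CD8, and the meningeal CD8 T cell share from -0.21 to 0.70. Alternatives planned for T cell receptor clones were not run, for lack of such chains in the tables used here. Depth was low in brain CD4 T cells, with 198 to 680 cells per library, and in meningeal CD8 T cells, with 180 to 672.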

Other observations

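All values in this part were looked at only after the data were seen, and none of them was tested.

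The contig tables differed in the isotype of their B cells, with 1 table per line and tissue. Cells with a switched isotype, one other than IgM or IgD, made up 41.4% of 350 paired cells in the TE4 brain table, 14.5% of 269 in the table labelled E4 and 5.71% of 385 in A-PE4. In the meninges the shares were 12.4% of 1986 cells in TE4, 7.66% of 2427 in the table labelled E4 and 6.62% of 2477 in A-PE4. In A-PE4, clones of 2 or more cells held 1.56% of paired cells in the brain and 5.69% in the meninges. One clone held 93 of the 141 clonal meningeal cells, and outside the largest clone of each table the shares were 0.785% and 2.01%. The largest clone of the TE4 brain table had 57 cells, and isotype shares were not computed without it. Barcodes of the A-PE4 brain table were found among kept cells of the A-PE4 CD45 high library in 428 of 429 cases. Those of the TE4 brain table were found in the TE4 CD45 high library of replicate 1 in 258 of 372. The E4 meninges replicate 1 library held 91 of these 372, so the TE4 brain values are not shown to come from TE4 cells alone. Those of the E4 brain table reached at most 3.85% in any library (1 of 286 in the E4 CD45 high library of replicate 1), and those of the E4 meninges table at most 3.08%, so the E4 values are not shown to come from the E4 libraries.

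Human APOE stood at like levels in border macrophages of both lines, with 15961 CPM in E4 brain, 20602 in TE4 brain, 20360 in E4 meninges and 19339 in TE4 meninges, all in replicate 1. In the same order, these values came from 40, 34, 330 and 746 cells. In microglia of the treated pair human APOE was at 16156 CPM with IgG and 3482 CPM with the antibodies. Of the 2 microglia clusters with P2ry12 and Tmem119 among their leading genes, that led by P2ry12 and Hspa1a held 3.77% of microglia with IgG and 15.8% with the antibodies, and that led by Ier3 and Atf3 28.1% and 42.6%. The cluster led by Lpl, Csf1 and Spp1 held 33.7% and 11.8%, and that led by Spp1, Cst7 and Apoc1 28.2% and 21.1%.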
